A study of Mus musculus with 2 samples.

How the data were processed

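RNA of single CD45+ aortic cells was measured in 2 libraries, 1 of eGFP-negative and 1 of eGFP-positive cells, each pooled from 5 mice. As deposited, each library was a sparse matrix of raw UMI counts per gene and barcode with no normalisation, made with the Chromium Single Cell 3' kit and Cell Ranger. The matrix headers give Cell Ranger 5.0.1, whereas the processing notes of the authors give Cell Ranger 3.0.1, Seurat 4.3.0.1 and build mm10. Per the file headers the values were whole-number counts, and every barcode in the files held at least 500 UMIs, so the lists of barcodes were already filtered. The deposited gene and barcode tables gave the row and column names, the same 32285 genes for both libraries, with no annotation release stated. Gene coordinates were taken from a mm10 annotation by gene ID, which found 275 of 276 genes looked up.

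Cells with at least 200 genes and at most 10% mitochondrial UMIs were kept. The mitochondrial limit removed 216 of 1095 barcodes (19.7%) of the library labelled GFP-negative and 237 of 4300 (5.51%) of the other. Scrublet, as implemented in scanpy 1.11.5, was run per library on the cells past these filters. It marked 5 of 879 cells (0.569%) and 6 of 4053 (0.148%), which is few for droplet libraries, so an alternative without the 5% highest doublet scores of each library was added after the data were seen. Counts were scaled to 10000 per cell and log-transformed, and both libraries were clustered together without integration on 2000 variable genes, 30 principal components and 15 neighbours, by the Leiden method at resolution 1 (igraph 0.11.9). The rest ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, with seed 0.

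The 26 clusters were named from 23 marker lists fixed before the data were examined and from the 10 genes leading each cluster, by fold over all other cells among genes found in at least 25% of its cells, with 0.05 per 10000 added to both means. Names of cell classes end in "-like" because they rest on these markers and not on an annotation by the authors. Of these clusters, 12 were called macrophage-like, and clusters led by dividing-cell genes and clusters of few UMIs without leading markers were left out of the class. Those choices were made after the clusters were seen. Clusters that lie mostly in 1 library may be a property of that library rather than a cell type.

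UMIs were summed over the cells of a class in each library, 12366155 and 33835520 UMIs for macrophage-like cells, and scaled to CPM, the UMIs of a gene per 1000000. Shares have exact Clopper-Pearson 95% intervals, CPM exact Poisson intervals and ratios exact conditional binomial intervals. A count of 0 was set to a floor of 3 counts in log2 ratios, and a share of 0 allows up to 3 counts of the total. These intervals cover counting error only and not variation between mice, which the pooled design with 1 library per group does not measure, so no p-value was computed. Ratios are the library labelled GFP-positive over the library labelled GFP-negative. Macrophage-like clusters were also weighted equally, over the 8 clusters with at least 20 cells in each library, and the 6 clusters with at least 50 cells in each were compared by themselves. Equal weights thus leave out macrophage-like clusters 9, 10, 11 and 13.

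Genes were named by a rule fixed before the data were examined. It took Lipa, Lyz2 and Ptprc, then the 12 highest and 12 lowest ratios in macrophage-like cells and the 5 highest and 5 lowest in each compared cluster. These were ranked by the interval bound nearer to 1 among genes with at least 100 UMIs over both libraries and 50 CPM in the higher, leaving out mitochondrial, ribosomal protein, immunoglobulin and T-cell receptor genes. It also took up to 4 members of each list. Erh and Gt(ROSA)26Sor were named in single clusters by this rule, and their values in other cells, and those of Acta2, were looked up after the data were seen. For 20 gene lists, also fixed before, the median log2 ratio was taken over members with at least 20 UMIs, with an order-statistic interval over the members. Its percentile among 10000 random lists matched on mean expression describes these 2 libraries and is no test.

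The ratio and list-median steps were run on simulated counts, drawn for each gene as independent Poisson counts from the pooled macrophage-like totals. Filters, doublet calls and clustering were not simulated. The ratio intervals assume the same model, so their coverage here checks the computation and not variation between cells or mice. Ratios set to 0.25, 0.5, 2 and 4 in 50 genes each came back as medians of 0.253, 0.499, 2.01 and 3.90. Among genes left at 1, 95.6% of the intervals held 1. A fold of 1.5 put on the lysosome list came back as 1.47 at percentile 100, with 0 of the 19 other lists in the outer 5%. Alternatives covered the cell filters, doublets, clustering resolution, clustering per library or without selected genes, scaling, averaging over cells, cluster weights, thinning to 3000 UMIs per cell and the list minimum. Other settings were added after the data were seen. Gene levels in lymphoid, dendritic and stromal classes were not compared as results, because no such class had 50 cells in both libraries.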

Results

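Transcripts of sorted plaque leukocytes were counted by 3' droplet single-cell RNA sequencing in 2 libraries. The cells came from aortas of male Ldlr-deficient mice that carried LysM-Cre and a Lipa open reading frame in the Rosa26 locus, and that had eaten a Western diet for 16 weeks. Lipa encodes lysosomal acid lipase, which hydrolyses cholesteryl esters and triglycerides, and eGFP marks cells in which Cre has recombined the transgene. CD45+ cells pooled from 5 mice were sorted into an eGFP-negative and an eGFP-positive library, called here by their labels. The genotype label of the library labelled GFP-negative reads LysMCre-/-, whereas the series description takes both libraries from mice with LysM-Cre. The library labelled GFP-negative held 1095 barcodes and 14472427 unique molecular identifiers (UMIs), and the library labelled GFP-positive held 4300 barcodes and 53446743 UMIs. After filtering, 874 and 4047 cells were kept, with medians of 12185 and 11271 UMIs. With 1 library per group there were no replicates and no test between the groups. Intervals of cell shares, CPM and ratios below are 95% intervals that cover counting error only. Those of list medians are 95% order-statistic intervals over the list members and do not cover counting error.

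Which leukocytes lay in each sort was described first. Macrophage-like cells, named from marker lists with genes such as Cd68, Csf1r and C1qa, made up 748 of the 874 kept cells of the library labelled GFP-negative (85.6%, 83.1 to 87.8, exact Clopper-Pearson) and 2496 of 4047 in the library labelled GFP-positive (61.7%, 60.2 to 63.2). No macrophage-like cluster had Cd68, Csf1r or C1qa among its 10 leading genes. Cluster 10 (17 and 147 cells), led by class II genes, had 0 listed macrophage markers among them. In at least 25% of its cells, 28 such markers were found. Dendritic-like cells of types 1 and 2 were 4 cells (0.458%) against 248 cells (6.13%). T cell-like cells numbered 1 against 83, and B cell-like cells 1 against 64. Mast cell-like cells numbered 0 of 874, which allows a share of up to 0.343%, against 49 (1.21%). Counted with the T and B cell-like cells, these lymphoid and mast cells were 0.229% (0.0277 to 0.824) against 4.84% (4.20 to 5.55). Stromal cells were also lower in the library labelled GFP-negative, at 31 cells (3.55%, 2.42 to 4.997) against 728 (17.99%, 16.8 to 19.2). Of these, fibroblast-like cells were 18 against 347 cells, smooth muscle-like cells 13 against 351, and endothelial-like cells 0 against 30. Dividing cells were 3.66% against 5.56% of kept cells, and cells in unnamed clusters 6.52% against 3.81%. No cluster was led by the markers of neutrophils, natural killer cells, plasmacytoid dendritic cells or erythroid cells, apart from Nkg7 in the T cell-like and Ly6d in the B cell-like cluster.

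The sort gates can set these shares, and the libraries differed 4047 to 874 in kept cells. Ptprc, which encodes CD45, the antigen of the sort, stood at 13.2 CPM (UMIs per 1000000 UMIs of the class and library; 11.1 to 15.6, exact Poisson) in stromal cells of the library labelled GFP-positive, against 212 CPM in its macrophage-like cells.

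**Figure D1:**
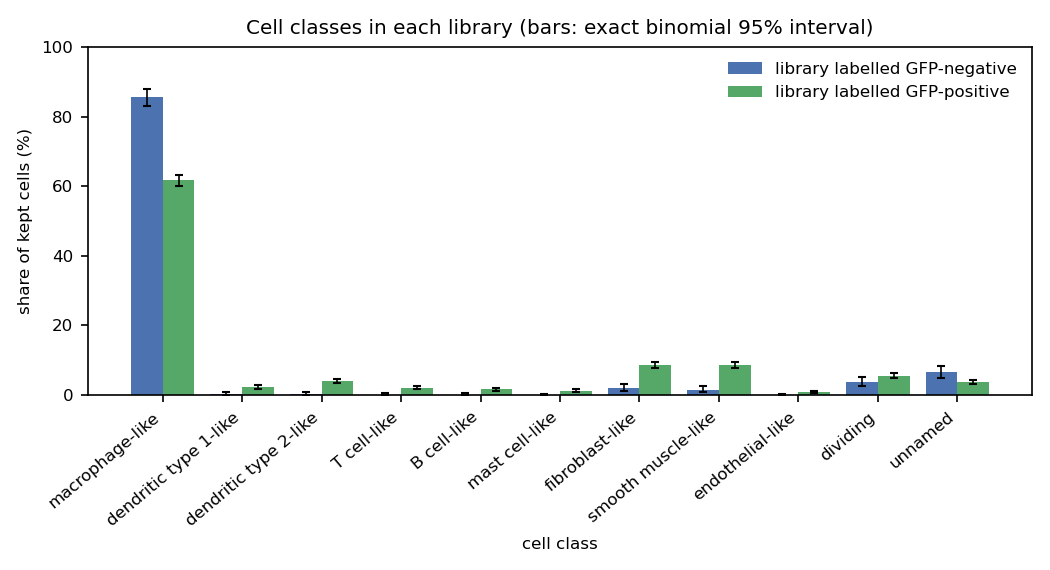
Share of kept cells (%, y axis) in each cell class (x axis) for the library labelled GFP-negative (blue, 874 cells) and the library labelled GFP-positive (green, 4047 cells), with bars for the exact Clopper-Pearson 95% interval. Macrophage-like cells were 85.6% and 61.7%, and the lymphoid, dendritic and stromal classes were almost all in the library labelled GFP-positive.

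Whether the sort separated cells by their Lipa transcript was asked in the macrophage-like cells. Lipa (ENSMUSG00000024781; mm10 chromosome 19, 34492318 to 34527474) stood at 400.2 CPM (389 to 412) in the library labelled GFP-negative and 482 CPM (474 to 489) in the library labelled GFP-positive, a ratio of 1.20 (1.17 to 1.24, exact conditional binomial). With the 8 clusters of at least 20 cells in each library weighted equally, the ratio was 0.996. Within the 6 clusters compared, Lipa was higher in 2, at 1.08 in resident-like cluster 1 and 1.10 in foamy-like cluster 2, and lower in 4, down to 0.755 in resident-like cluster 3. The counting interval lay above 1 in cluster 2 only and below 1 in clusters 0, 3 and 6, and included 1 in clusters 1 and 8. Lyz2 (ENSMUSG00000069516; chromosome 10, 117277331 to 117282321), the gene whose promoter drives LysM-Cre, stood at 10114 and 9885 CPM, a ratio of 0.977 (0.971 to 0.984) that rose above 1 under median-of-ratios scaling and other settings. Ptprc (ENSMUSG00000026395; chromosome 1, 138062861 to 138175708) stood at 253 and 212 CPM, a ratio of 0.840 (0.805 to 0.876). A Lipa UMI was present in 86.1% (83.4 to 88.5) and 84.0% (82.5 to 85.4) of macrophage-like cells at median depths of 12560 and 11555 UMIs. After each cell was thinned to 3000 UMIs, which left out 37 and 118 shallower cells, the shares were 58.6% and 61.5%. In smooth muscle-like cells of the library labelled GFP-positive, the share was 30.2% at a median of 12599 UMIs and 10.8% after thinning. In the library labelled GFP-negative it was 69.2% (38.6 to 90.9) of 13 such cells at a median of 19078 UMIs, and 7.69% (0.195 to 36.0) after thinning. Among named classes of the library labelled GFP-positive, Lipa CPM was lowest in smooth muscle-like cells, at 34.2. It was 82.7 in endothelial-like cells. Whether the Lipa UMIs of these classes were free RNA or transcripts of the cells themselves was not tested. The Lipa ratio in smooth muscle and fibroblast-like cells was 0.633 (0.463 to 0.885), and 0.468 (0.287 to 0.809) in smooth muscle-like cells alone. The table of 32285 genes had 0 features named eGFP or Cre, and the labels do not say whether transcripts of the transgene, which holds the open reading frame, are counted as Lipa by 3' reads.

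The main comparison asked how plaque macrophages of the library labelled GFP-positive differed from those of the library labelled GFP-negative. Lyz1, a lysozyme gene, had the highest ratio by the naming rule, at 566 against 285 CPM (ratio 1.99, 1.92 to 2.06). It was higher in all 6 compared clusters, except that it turned in cluster 2 under 2 alternative filters. The macrophage-like clusters not compared held most of the 3520 Lyz1 UMIs of the library labelled GFP-negative. Pooled over those clusters, Lyz1 CPM was lower in the library labelled GFP-positive. By the naming rule, Lyz1 was followed by Mmp14, a membrane-bound matrix metalloproteinase (1.85, 1.69 to 2.03). Next was Acp5, tartrate-resistant acid phosphatase and a leading gene of foamy-like cluster 7 (1.73, 1.65 to 1.80). Members of the lysosome list or of the foamy macrophage markers were Lgals3 (galectin-3, 1.63), Ctsd (the protease cathepsin D, 1.62) and Psap (the saposin precursor, 1.62). The other members were Cadm1 (1.78, also a marker of type 1 dendritic cells), Slc6a8 (the creatine transporter, 1.68), Ndrg1 (1.67), Il7r (the interleukin-7 receptor, also a marker of innate lymphoid cells, 1.62), Dnmt3a (a DNA methyltransferase, 1.605) and Basp1 (1.56). All 12 were also above 1 with clusters weighted equally, Lyz1 at 3.08 and the others between 1.20 for Il7r and 1.46 for Cadm1. In smooth muscle and fibroblast-like cells, Lgals3 (1.27, 1.15 to 1.42), Ctsd (1.58) and Psap (1.27) were higher too, with Lgals3 at 4.29 (2.63 to 7.52) in smooth muscle-like cells alone, and the intervals of the other 9 included 1. Lyz1 (ENSMUSG00000069515; chromosome 10, 117287797 to 117292868) is among the leading genes of cluster 0 and shares 21.9% of its 3' 50-base words with another gene.

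**Figure D2:**
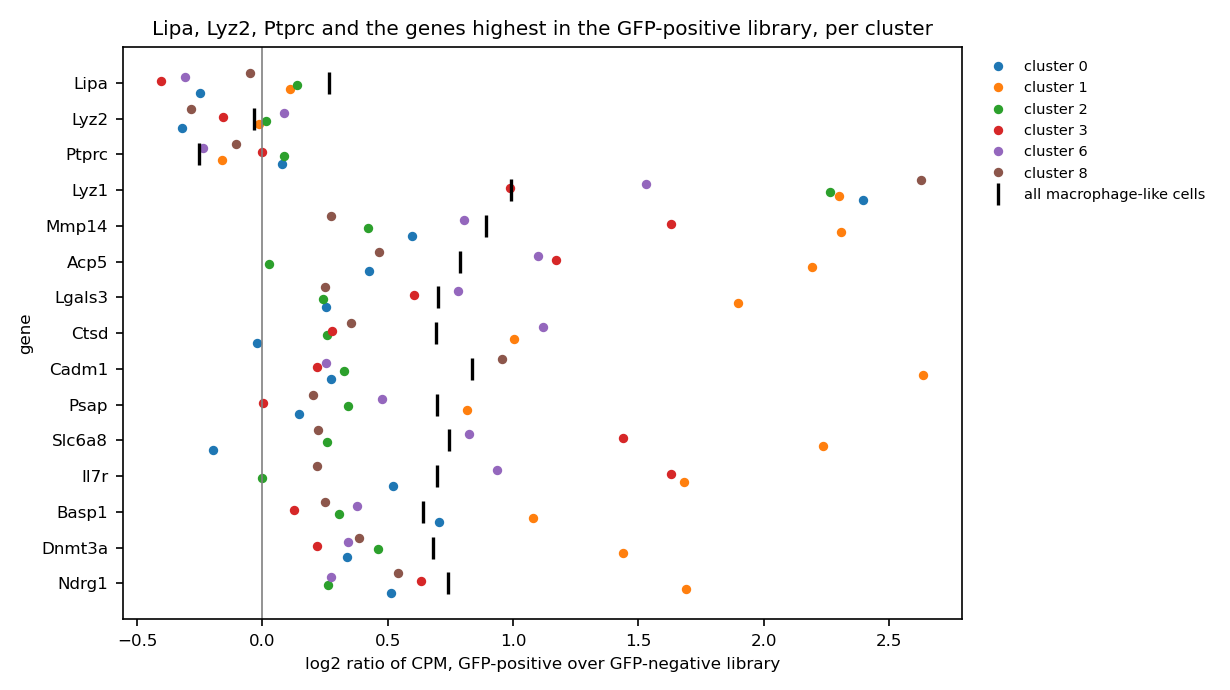
Log2 ratio of CPM in the library labelled GFP-positive over the library labelled GFP-negative (x axis) for Lipa, Lyz2, Ptprc and the 12 highest genes (y axis). Each point is 1 of the 6 compared macrophage-like clusters, and each black bar is all macrophage-like cells. Points for Lipa lie on both sides of 0 and its bar is at 0.27, whereas Lyz1 lies above 0 in all 6, though in cluster 2 not under 2 alternative filters.

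The 12 lowest genes fell into 3 sets. Slpi (a protease inhibitor, ratio 0.0372), Saa3 (a serum amyloid A protein, 0.0403), Marco (a scavenger receptor, 0.102), Cxcl13 (a B cell chemokine, 0.124) and Timd4 (a phosphatidylserine receptor of resident macrophages, 0.204) lead cluster 9, which held 23 and 19 cells. Without this cluster, an alternative chosen after seeing the data, the log2 ratio of Slpi went from −4.75 to 0.78 and that of Marco from −3.30 to 0.29. Equal weights leave out cluster 9 as well, because it lacks 20 cells in each library. With clusters weighted equally, and so without cluster 9, the ratios of Saa3, Cxcl13 and Timd4 were 0.691, 0.846 and 0.768. The lectin genes Fcna (0.257), Cd209f (0.263) and Cd209g (0.284) lead resident-like cluster 3, and the chemokine gene Ccl24 (0.259) leads resident-like cluster 1. With clusters weighted equally, these 4 ratios lay between 0.771 for Ccl24 and 0.972 for Cd209g. Clusters 1 and 3 held 167 and 120 of the 748 macrophage-like cells of the library labelled GFP-negative, against 300 and 112 of 2496 in the other. Among macrophage-like clusters, the largest in both libraries was inflammatory-like cluster 6 (170 and 424 cells). It was followed in the library labelled GFP-positive by the foamy-like clusters 8 (389 cells) and 7 (331 cells).

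Uba52, a ubiquitin and ribosomal protein fusion gene (ratio 0.170, 0.165 to 0.176), Gstp1, a glutathione transferase (0.207, 0.190 to 0.225), and Bloc1s1, a subunit of a lysosome-related organelle complex (0.261, 0.237 to 0.287), made up the third set. They were lower in all 6 compared clusters. In smooth muscle and fibroblast-like cells their ratios were 0.153 for Uba52, 0.272 for Gstp1 and 0.229 for Bloc1s1. Of their 3' 50-base words, 96.4% for Uba52, 100% for Gstp1 and 83.3% for Bloc1s1 also occurred in another gene. Erh, named in 4 single clusters, was lower too, at 154 and 61.7 CPM in macrophage-like cells, with a ratio of 0.398 in smooth muscle and fibroblast-like cells.

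**Figure D3:**
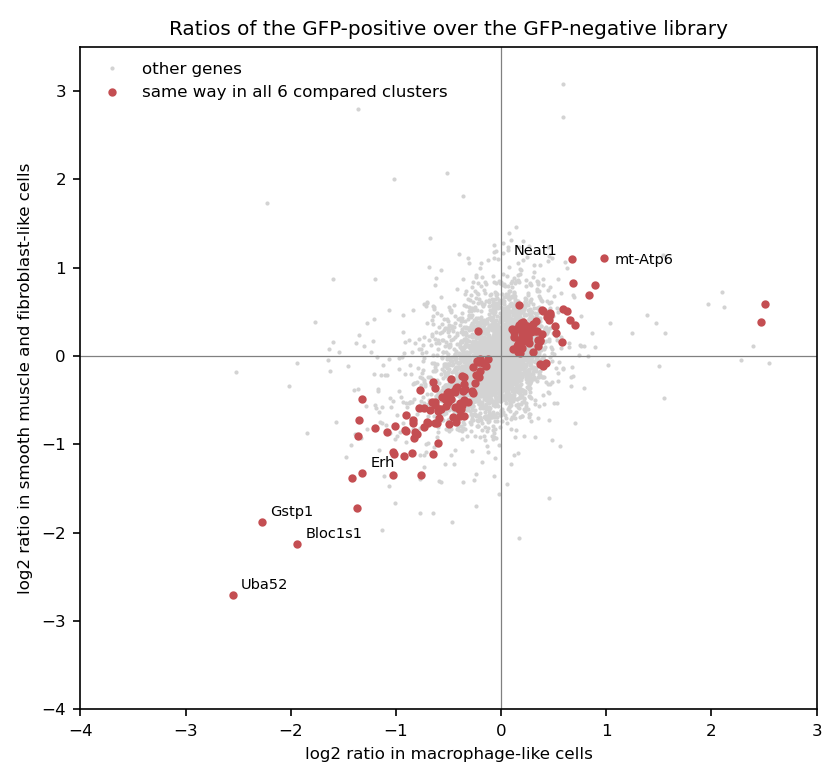
Log2 ratio of the library labelled GFP-positive over the library labelled GFP-negative in macrophage-like cells (x axis) and in smooth muscle and fibroblast-like cells (y axis). Each point is 1 of 3845 genes, with at least 100 UMIs in the first and 300 in the second cells; 5 genes lie outside the axes, and red points have a counting interval on the same side of 1 in all 6 compared clusters. Red points lie along the diagonal, with Uba52 at −2.55 and −2.71.

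Genes of lysosomes and of lipid handling were mostly higher in the library labelled GFP-positive, and genes of cholesterol synthesis mostly lower. Of 30 lysosome genes, 22 were higher and 8 lower, with a median log2 ratio of 0.18 (0.12 to 0.36 over the members) at percentile 99.8 of 10000 random lists matched on expression. Examples were Ctsd, Psap, Atp6v0d2 (a proton pump subunit, 1.53) and Cd63 (a lysosomal membrane tetraspanin, 1.44). Of 15 targets of LXR, the nuclear receptor of oxysterols, 13 were higher (median 0.24, 0.18 to 0.44, percentile 99.98). Among them were Lpl (lipoprotein lipase, 1.52), Lpcat3 (a phospholipid-remodelling enzyme, 1.44), the cholesterol exporter gene Abcg1 (1.37) and Apoe (1.28), the last at 34514 and 44296 CPM. Of 20 genes of cholesterol synthesis, 15 were lower (median −0.29, −0.57 to −0.06, percentile 8). They included Sqle (squalene epoxidase, 0.337, with 26 and 24 UMIs), Stard4 (0.402), Insig1 (0.523) and Idi1 (0.544). Lipid uptake and storage had 12 of 18 genes higher (median 0.10, −0.31 to 0.46), with Fabp5 and Plin2 at 1.51 and 1.46 and Olr1 at 0.125. Fatty acid oxidation had 10 of 15 measured genes higher (median 0.10, −0.14 to 0.17), among them Pparg (1.49), Hadha (1.20) and Etfb (1.19), with Ppargc1b at 0.564. With clusters weighted equally the medians were 0.10 for lysosome genes (percentile 97.0), 0.17 for LXR targets (99.7) and −0.34 for cholesterol synthesis (0.02). They were 0.07 for lipid uptake and storage and 0.03 for fatty acid oxidation. The median log2 ratio of all 9960 genes with at least 100 UMIs was −0.08. List medians of smooth muscle and fibroblast-like cells, with 31 cells in the library labelled GFP-negative, were added after the result was seen. These cells mix clusters 12 (8 and 301 cells), 16 (10 and 46) and 17 (13 and 351, all the smooth muscle-like cells), so the mix can shift their ratios, and smooth muscle-like cells were also taken alone. The medians of the mixed cells were 0.06 for lysosome genes (percentile 90.2), −0.02 for LXR targets and −0.22 for cholesterol synthesis, each with an interval that included 0, as were 0.05, −0.25 and −0.44 in smooth muscle-like cells alone. Single genes were also higher in the mixed cells, such as Ctsd (1.58, 1.39 to 1.81), Psap (1.27), Cd63 (1.17), Lpl (2.09), Apoe (1.23), Fabp5 (6.54) and Plin2 (1.82), whereas the intervals of Abcg1 (0.748), Lpcat3 (0.780), Atp6v0d2 (1.34), Insig1 (0.417) and Idi1 (0.788) included 1. In smooth muscle-like cells alone, Ctsd (1.83), Cd63 (1.44) and Fabp5 (1.93) stayed higher, Psap, Lpl and Plin2 had intervals that included 1, and Apoe (0.796) and Insig1 (0.247) were lower.

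Inflammatory, chemokine and alternative activation genes were mostly lower in the library labelled GFP-positive when all macrophage-like cells were pooled. Of 20 NF-kB targets, 16 were lower (median −0.47, −0.74 to −0.10, percentile 0.01), including the cytokine gene Il6 (0.183, with 46 and 23 UMIs) and the chemokine genes Ccl2 (0.431), Cxcl2 (0.455) and Ccl4 (0.586). Of 14 measured genes of monocyte recruitment, 13 were lower (median −0.52, −1.39 to −0.30, percentile 0), such as Pf4 (0.383) and Ccl7 (0.381), both leading genes of cluster 1. The exception was the monocyte marker Ly6c2 (6.42, with 9 and 158 UMIs). All 13 genes of alternative activation were lower (median −1.18, −1.58 to −0.26, percentile 0), including Cd163 (0.324), Retnla (0.335) and Lyve1 (0.383), which lead the resident-like clusters 1 and 3. Of 19 measured interferon response genes, 16 were lower (median −0.30, −0.86 to −0.14, percentile 0.6), such as Oas1a (0.449), Ifitm3 (0.458), Ifi204 (0.536) and Irf7 (0.536). Efferocytosis, the uptake of dying cells, had 11 of 18 genes lower (median −0.15, −0.71 to 0.08), with Timd4, Pros1 (0.531), Gas6 (0.602) and Mfge8 (0.613) the lowest. Of 18 early response genes, which tissue dissociation can induce, 17 were lower (median −0.59, −0.76 to −0.42, percentile 0), such as Hspa1b (0.442), Egr1 (0.447), Ier3 (0.531) and Zfp36 (0.590). With clusters weighted equally these medians were closer to 0, at −0.04 for NF-kB, −0.07 for monocyte recruitment, −0.07 for alternative activation, −0.04 for efferocytosis and −0.13 for early response genes. That of the interferon response turned to 0.22, and Irf7, Gas6, Il6 and Lyve1 also turned. The equally weighted clusters leave out interferon-inducible-like cluster 13 (10 and 52 cells), led by Ifit3, Isg15 and Irf7 among others. For interferon genes, the effect of equal weights and that of leaving out this cluster cannot be told apart. In smooth muscle and fibroblast-like cells the medians were −0.29 for NF-kB, −0.78 for monocyte recruitment, −0.74 for alternative activation, −0.36 for early response genes and 0.22 for the interferon response, with intervals that included 0. Efferocytosis was at −0.22 (−0.38 to −0.02). Il6 (0.115), Cxcl2 (0.256), Ccl7 (0.541), Pf4 (0.228), Cd163 (0.138) and Egr1 (0.643) were lower there too, whereas Ccl4 was higher (3.27, 1.26 to 12.1), as was Retnla, with 0 against 83 UMIs (ratio interval from 1.18), and the intervals of Ccl2, Ifitm3, Ier3 and Hspa1b included 1. In smooth muscle-like cells alone the medians were −0.62 for NF-kB, −3.04 for monocyte recruitment (percentile 0), −1.55 for alternative activation (0.035), −0.52 for early response genes (0), −0.18 for efferocytosis and −0.14 for the interferon response, all with intervals that included 0. There Cxcl2, Ccl7, Ccl2, Pf4, Cd163 and Egr1 were lower, and the intervals of Il6, Ccl4 and Retnla included 1. The library labelled GFP-negative held 13 of these cells, with a Lyz2 UMI in 23.1% of them and a Ptprc UMI in 7.69%. How many of the 13 cells carried the macrophage genes above was not counted, and the intervals do not cover RNA concentrated in few cells. Barcodes over the mitochondrial limit, which were removed, were 19.7% of the library labelled GFP-negative and 5.51% of the other, so a difference in handling was not excluded.

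Antioxidant targets of NRF2 were higher, 12 of 14, in the library labelled GFP-positive (median 0.31, 0.07 to 0.53, percentile 100; 0.17 with clusters weighted equally). The ferritin chains Ftl1 (1.44) and Fth1 (1.31) and the cystine transporter gene Slc7a11 (2.39, with 39 and 255 UMIs) were examples, whereas Hmox1, heme oxygenase 1, stood at 0.778 and turned above 1 with equal weights. In smooth muscle and fibroblast-like cells the NRF2 median was 0.18 (−0.11 to 0.53), with Fth1 at 1.44 and Ftl1 at 1.19, and in smooth muscle-like cells alone it was 0.39 (0.11 to 1.41). Extracellular matrix and protease genes were higher in 12 of 20 (median 0.12, −0.08 to 0.89, percentile 98.6; 0.23 with equal weights). Mmp14 was among them, with Col1a1 (5.25, from 8 and 115 UMIs) and Sparc (2.91), while Mmp9, also a neutrophil marker, stood at 0.371 and turned above 1 with equal weights. Col1a1 is a fibroblast marker, and the smooth muscle marker Acta2 stood at 2.51 and 14.3 CPM in the macrophage-like cells of the 2 libraries. MHC class II genes were higher in 8 of 9 (median 0.12, 0.05 to 0.16, percentile 84.1), with H2-Aa at 1.12, H2-DMb1 at 1.11 and Cd74 at 1.09. The exception was H2-Eb1 (0.952, above 1 under median-of-ratios scaling), and the list median fell to −0.03 when each library was clustered on its own.

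The remaining lists had medians within 0.1 of 0. Oxidative phosphorylation had 10 of 20 genes higher (median 0.00), with Cox4i1 at 1.42 against Ndufa1 at 0.672, Cox6c at 0.741 and Atp5e at 0.749. Glycolysis had 11 of 17 genes higher (median 0.04), with Pkm at 1.23 and Pgam1 at 1.22 against Hk2 at 0.586 and Eno1 at 0.661. Integrins had 10 of 15 measured genes lower (median −0.07), such as Itgb3 (0.494), Itgam (0.575), Itgal (0.596, above 1 with equal weights) and Itgb1 (0.719). Autophagy had 10 of 16 genes lower (median −0.03), with Gabarap at 1.19, Map1lc3b at 1.16 and Sqstm1 at 0.858. The unfolded protein response was split 7 to 7 (median 0.01), with Calr at 1.29 against Dnajb9 at 0.704, Pdia4 at 0.757 and Herpud1 at 0.763. Cell division had 13 of 20 genes lower (median −0.05), such as Hells (0.539), Aurkb (0.557) and Mki67 (0.656). The last 2 turned when dividing cluster 14 and low-UMI cluster 5 were added to the class. That alternative, chosen after seeing the data, took the list median to 0.37. In smooth muscle and fibroblast-like cells, extracellular matrix genes had a median of 0.35 (0.10 to 0.49), while lists lower with an interval below 0 were cell division (−2.16), MHC class II (−1.11), glycolysis (−0.30), efferocytosis and fatty acid oxidation (−0.18). In smooth muscle-like cells alone only cell division (−2.05) and MHC class II (−1.79) kept intervals without 0 among these lists, and the glycolysis median turned to 0.14 (−0.24 to 0.42). The library labelled GFP-negative held only 13 smooth muscle-like cells.

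**Figure D4:**
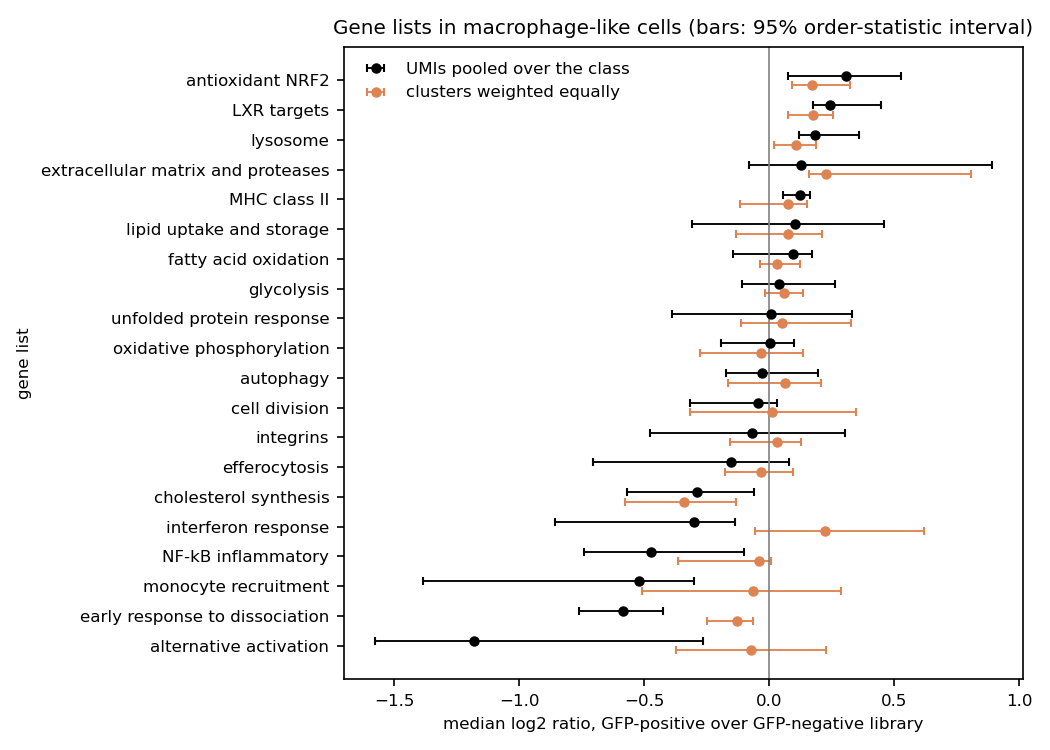
Median log2 ratio of the library labelled GFP-positive over the library labelled GFP-negative (x axis) for 20 gene lists (y axis) in macrophage-like cells. Points are medians over the measured members, black with UMIs pooled over the class and orange with clusters weighted equally, and bars are 95% order-statistic intervals over the members. Alternative activation moves from −1.18 to −0.07, whereas cholesterol synthesis is at −0.29 and −0.34.

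Macrophage-like clusters with at least 50 cells in each library were then compared by number. In resident-like cluster 1 (167 and 300 cells), the highest genes were Atp6v0d2 (ratio 12.9, 6.66 to 28.6), Fabp4 (10.9, 6.14 to 21.5), Gpnmb (6.66, 5.46 to 8.19), Lyz1 (4.92) and Fabp5 (4.51), of which Gpnmb and Fabp5 are foamy macrophage markers. The chemokine gene Ccl12 was lower there, at 1609 and 722 CPM. Lysosome genes of this cluster were higher in 26 of 30 (median 0.32, percentile 100), against medians of 0.24 in cluster 6, 0.10 in cluster 2, 0.09 in cluster 8, 0.01 in cluster 3 and −0.01 in cluster 0, and the ratio of Fabp4 turned below 1 at clustering resolution 0.5. In resident-like cluster 3 (120 and 112 cells), Spp1, which encodes osteopontin (4.21, 3.15 to 5.70), the long non-coding RNA Neat1 (2.68) and the interferon-induced genes Ifit3 (2.42) and Ifit1 (1.94) were higher. Spp1 stood at only 41.3 and 174 CPM there, below 138 and 299 CPM in smooth muscle-like cells. In those smooth muscle-like cells Spp1 (2.16, 1.54 to 3.14) and Neat1 (2.89, 1.39 to 7.24) were also higher, and the intervals of Ifit3 and Ifit1 included 1. The lowest genes of cluster 3, after Uba52 and Gstp1, were Dctn4, Erh and Gt(ROSA)26Sor, a non-coding RNA of the Rosa26 locus (0.393, 0.286 to 0.532). In all macrophage-like cells Gt(ROSA)26Sor stood at 91.6 and 35.6 CPM (0.389), with 0.535 in smooth muscle and fibroblast-like cells.

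In foamy-like cluster 8 (58 and 389 cells), led by Clec4d and Spp1, antigen presentation genes were higher in the library labelled GFP-positive: H2-Aa (3.55, 2.75 to 4.65), Cd74 (3.29, 2.97 to 3.66) and H2-Ab1 (2.56, 2.06 to 3.21). Lyz1 (6.18) and Cadm1 were also higher there, while the resident marker Folr2 (0.402) and the protease gene Ctsk (0.230) were lower. The log2 ratio of Ctsk turned to 1.21 when cells needed at least 1000 genes. In inflammatory-like cluster 6 (170 and 424 cells), Ctsd (2.17), Spp1 (1.93), Gpnmb (2.40), Lyz1 (2.89) and the neuropeptide gene Npy were higher, and the lectin gene Mgl2 (0.272, 0.242 to 0.306) was lower. The LXR targets of cluster 6 were higher in 14 of 15 (median 0.35, percentile 100), and its cholesterol synthesis genes lower in 13 of 17 (median −0.55, percentile 0.03). Neither held in every cluster, with LXR medians of −0.12 in cluster 0 and 0.03 in cluster 3, and cholesterol synthesis higher in 9 of 13 and 5 of 9 genes there (0.26 and 0.15).

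In cluster 0 (61 and 235 cells), led by Ccr2 and Clec4b1, the chemokine gene Ccl17 had 0 UMIs against 222 (ratio interval from 21.5). Its log2 ratio was 4.74 with the count of 0 set to the floor of 3 UMIs. The monocyte marker Plac8 (23.1, 10.5 to 63.3), Lyz1 (5.27), Slpi (52.3, 9.24 to 2081, from 1 and 145 UMIs) and the dendritic cell marker Cd209a were also higher, and the neutrophil marker S100a8 (0.0245, with 103 and 7 UMIs) was lower. Ccr2 is on the marker lists of monocytes and of cavity macrophages, and Cd209a is a leading gene of type 2 dendritic-like cluster 19 (2 and 157 cells). Whether monocytes or dendritic cells lay in cluster 0 was not tested. In cluster 0 H2-M2 stood at 0.200 but turned above 1 under 2 other settings. In foamy-like cluster 2 (53 and 282 cells), led by Gpnmb and Fabp5, Cd74 (1.70, 1.601 to 1.81), the calcium-binding protein gene S100a4, Cdkn1c, Stab1 and Lyz1 (4.81) were higher. Retnla, a leading gene of cluster 3, was lower, with 125 and 1 UMIs (0.00243, 6.1e-05 to 0.0138). Other leading genes of cluster 3 were near absent from the same 53 cells, with 1 UMI of Cd209f, 0 of Cd209g and 3 of Fcna. How many cells held the Retnla UMIs was not counted, and the interval does not cover RNA concentrated in few cells. S100a4 and Lyz1 turned in cluster 2 under 2 other settings each. Uba52, Gstp1, Bloc1s1, Erh, Polr2l and Gm11808 made up most of the other lowest genes in the 6 clusters. No other named class reached 50 cells in both libraries, so genes were not compared within the lymphoid, dendritic or stromal classes, apart from the smooth muscle and fibroblast-like cells used above as a reference.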

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

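The tests of exchanged labels, of a library-wide difference (also in smooth muscle-like cells alone) and of the mix of macrophage-like clusters, and the rank correlation with transcript length, were chosen only after the result was seen.

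The lymphoid, dendritic and stromal classes lay almost all in the library labelled GFP-positive, although LysM-Cre is known to act mainly in myeloid cells. For T, B, smooth muscle and fibroblast-like cells, the tables argue against macrophages carrying RNA of other cells. The median of 10 macrophage markers in these classes reached at most 0.138 of the macrophage-like level, in the B cell-like class. Dendritic, mast and endothelial-like cells were not checked in this way. Stromal cells without CD45 in the gate remain a candidate explanation for the stromal part, because Ptprc in them stood at 0.0621 (0.0521 to 0.0735) of its level in macrophage-like cells. An exchange of the labels cannot be told apart from correct labels, since the Lipa ratio over equally weighted clusters was 0.996 and the reads may miss the transgene. Recombination outside the myeloid lineage was not tested and also stays open.

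Genes shifted the same way in all 6 compared clusters, such as Uba52, Gstp1 and Bloc1s1, tended to be shifted alike outside the macrophages. Markers apart, these were 164 genes, 97 lower and 67 higher. Ribosomal protein and mitochondrial genes, which the naming rule left out, were kept among them. Of this set, 98.2% (94.7 to 99.6, exact binomial over genes) were shifted the same way in smooth muscle and fibroblast-like cells. Expression-matched genes gave a median of 53.0%, with a full range of 40.9 to 66.5 over 1000 random draws. They were not matched on gene family, and genes of a family need not shift independently. The interval over genes and the comparisons below may therefore partly reflect ribosomal protein genes. In smooth muscle-like cells alone, which form 1 cluster, the values were 94.4% against 51.6%. This is consistent with a difference between the libraries in every cell type, while sequence shared with paralogs or pseudogenes is a further candidate explanation, with a share of such genes 2.19 times that of expression-matched genes (26.4% against 12.05%). Transcript length stays unresolved, because the lower genes had a median length 0.585 of that of matched genes (1178 against 2014.5 bases, with the higher genes at 1248 against 1545) while the correlation of length and log2 ratio across 9399 genes, which are not independent replicates, had the opposite sign (Spearman's rho −0.17). An effect of the transgene on these genes was not tested and stays open.

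The alternative activation list was lower in all macrophage-like cells of the library labelled GFP-positive, at a median log2 ratio of −1.18. The tables argue against free RNA of resident-like cells in the other library, since the list summed to 172 CPM (139 to 211) in its smooth muscle and fibroblast-like cells, 0.101 of the gap of 1709 CPM between the libraries. A different mix of macrophage-like clusters stays a candidate explanation, and with equal weights the median kept 0.0625 of its size. However, list members such as Cd163, Mrc1, Retnla and Lyve1 lead clusters 1 and 3, which were found from the same data. Equal weights therefore cannot tell a changed mix from a change of these genes that moved cells between clusters. Why the mix differed was not tested, and the sort and the recombination stay open.

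Some list medians pointed in opposite directions in different clusters, and these differences were not tested. The interferon response had a median log2 ratio of 0.34 in cluster 3 and −0.45 in cluster 6. MHC class II genes had 1.04 in cluster 8 and −0.21 in cluster 1. Early response genes had 0.30 in cluster 2, −0.27 in cluster 1 and −0.28 in cluster 6. Cell division genes had 0.72 in cluster 8 and −0.53 in cluster 6.

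Signals also lay in cells that no comparison used. An unnamed cluster led by Msln and Upk3b, genes of mesothelial cells, held 0.321% of kept cells of the library labelled GFP-positive and 0 cells of the other. Barcodes over the mitochondrial limit were 19.7% of the library labelled GFP-negative and 5.51% of the library labelled GFP-positive.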

How the results depend on the processing

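Of 360 list medians over 18 alternatives, 342 stayed within the interval of the main value, 16 moved and 2 reversed. Of 60 class shares, 46 stayed and 14 moved, and no reversal was defined for shares. A log2 ratio or list median counted as reversed only if its sign turned and its main interval excluded 0. Lists whose main interval included 0 could therefore not count as reversed. Of 99 genes named in macrophage-like cells, 85 never reversed over 16 alternatives, and of 60 pairs of a named gene and a cluster, 55 never reversed over 14. Sizes moved more often: of the 1584 macrophage-like gene values, 1200 stayed, 358 moved and 26 reversed, and of 820 values of such pairs, 614 stayed, 198 moved and 8 reversed. Equal weights moved 68 of 99 genes, thinning 64, a mean over cells 59 and median-of-ratios scaling 50. The last 3 alternatives below (dividing and low-UMI clusters included, high doublet scores removed, cluster 9 removed) were chosen after seeing the data. The first of these added dividing cluster 14 and low-UMI cluster 5 only, and left out dividing cluster 25 and low-UMI cluster 4. Equal weights do not apply to single clusters, and a cluster with under 20 cells in either library gave no value. The cause of each change was not tested, except that equal weights and the removal of cluster 9 change the mix of clusters by construction, and thinning lowers the share of cells with a UMI. Depth limits genes with few UMIs, such as Il6, Sqle and Col1a1, and no alternative stands in for replicate libraries.

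Macrophage-like shares of the libraries labelled GFP-negative and GFP-positive moved from 85.6% and 61.7% to 91.6% and 66.3% at a mitochondrial limit of 5%, 90.3% and 65.3% with at least 1000 genes, and 89.4% and 64.99% at resolution 0.5. They moved to 91.8% and 65.3% in clustering without Lipa, Lyz2, mitochondrial, ribosomal protein and early response genes, and to 93.6% and 70.1% with dividing and low-UMI clusters included. The share in the library labelled GFP-positive was 64.3% when each library was clustered on its own. In that library, stromal cells were 15.9% at the 5% limit and lymphoid and mast cells 3.33% with at least 1000 genes, and lymphoid and mast cells of the other library were 0% when clustered on their own. Shares of macrophage-like cells with a Lipa UMI were 58.6% and 61.5% after thinning.

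With clusters weighted equally, list medians moved to 0.10 for lysosome, 0.17 for LXR targets, −0.043 for NF-kB, −0.067 for monocyte recruitment, −0.074 for alternative activation and −0.13 for early response, and that of the interferon response reversed to 0.22. Log2 ratios reversed to −0.0060 for Lipa, 0.67 for Slpi, 1.17 for Marco, 0.064 for Il6, 0.18 for Irf7, 0.15 for Itgal, 0.16 for Mmp9, 0.071 for Gas6, 0.047 for Hmox1 and 0.068 for Lyve1. Equal weights also leave out cluster 9, which Slpi and Marco lead, and cluster 13, which interferon-induced genes lead. The MHC class II median was 0.17 at a mitochondrial limit of 20%, 0.20 under median-of-ratios scaling, 0.023 after thinning, 0.24 with dividing and low-UMI clusters, 0.23 without high doublet scores and, reversed, −0.027 when each library was clustered on its own. Median-of-ratios scaling gave 0.17 for fatty acid oxidation and 0.033 for cell division. Thinning gave 0.48 for LXR targets and 0.069 for cell division, which was 0.37 with dividing and low-UMI clusters.

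Log2 ratios of single genes reversed as follows. Lyz2 went to 0.00084 when each library was clustered on its own, 0.046 under median-of-ratios scaling, 0.087 as a mean over cells, 0.088 after thinning and 0.0036 without high doublet scores. H2-Eb1 went to 0.0086 under median-of-ratios scaling, 0.034 with dividing and low-UMI clusters and 0.059 without high doublet scores. Mki67 went to 0.038 at resolution 0.5, 0.38 after thinning and 0.50 with dividing and low-UMI clusters, and Aurkb to 0.13 and 0.10 in the last 2 of these. Without cluster 9, Slpi went to 0.78, Marco to 0.29 and Itgal to 0.20. Lyz1 in cluster 2 went to −0.62 at a mitochondrial limit of 20% and −0.36 with at least 1000 genes, where Ctsk in cluster 8 went to 1.21. H2-M2 in cluster 0 went to 1.34 with doublets kept and 0.67 in clustering without Lipa, Lyz2, mitochondrial, ribosomal protein and early response genes. At resolution 0.5, Fabp4 in cluster 1 went to −0.38 and S100a4 in cluster 2 to −0.032, the latter to −1.31 when each library was clustered on its own.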

Other observations

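Other gene lists differed within macrophage-like clusters. In inflammatory-like cluster 6, 15 of 19 measured NF-kB genes were lower in the library labelled GFP-positive (median log2 ratio −0.29, −0.49 to −0.10, percentile 0.01), as were 12 of 14 cell division genes. In foamy-like cluster 8, 12 of 17 NF-kB genes were higher (median 0.37, percentile 100), with an interval that included 0 (−0.08 to 0.68), and 9 of 10 cell division genes were higher. In resident-like cluster 3, 11 of 16 NF-kB genes were lower (median −0.36, −0.54 to 0.17). Antioxidant NRF2 targets were higher in 12 of 12 measured genes of resident-like cluster 1 (median 0.48) and in 11 of 12 of cluster 8 (median 0.22), but in 5 of 12 of resident-like cluster 3 (median −0.07). Extracellular matrix and protease genes were higher in 12 of 13 genes of cluster 3 (median 1.12) and in 12 of 15 of cluster 1 (median 0.46). This list holds fibroblast markers such as Col1a1. The smooth muscle marker Acta2, which is outside the list, was also higher in all 6 compared clusters, with each counting interval above 1. None of these differences between clusters was tested.

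RNA of other cell types was found in macrophage-like cells at different levels in the 2 libraries. Igkc, an immunoglobulin light chain gene of B lineage cells, stood at 0.809 CPM in the library labelled GFP-negative and 11.7 CPM in the library labelled GFP-positive. Myl9, a smooth muscle gene, stood at 0.647 and 2.81 CPM, and S100a8, a neutrophil gene, at 23.9 and 9.75 CPM. Mitochondrial genes took 1.39% and 2.10% of macrophage-like UMIs, and ribosomal protein genes 15.2% and 14.4%. The mitochondrial gene mt-Atp6 stood at 2314 and 4572 CPM, with a ratio of 1.98 in macrophage-like and 2.15 in smooth muscle and fibroblast-like cells, whereas mt-Atp8 (0.436 and 0.568) and mt-Nd4l (0.473 and 0.549) were lower in both. Of the nuclear long non-coding RNAs, Neat1 had ratios of 1.59 and 2.13 in the same cells, while the more abundant Malat1 had 0.497 and 0.579.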
